A study of Mus musculus with 4 samples.

How the data were processed

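Nuclear RNA of mouse retina was profiled by the submitters with the 10x single-nucleus RNA method in 4 libraries, each from 1 left eye, 2 from animals of 2.5 months and 2 from animals of 5 months. The sample labels number the donors and the series describes its donors as unrelated, so each library was treated as 1 animal and 1 replicate. The series title names human retina and its text an eye bank, so that the description may not concern these mice. Xist and Y-linked genes show 1 library of either sex at each age, so the 2 libraries of an age came from different animals. The authors deposited raw UMI counts per gene and barcode for 31053 genes; the deposited counts are whole numbers and no barcode holds fewer than 500 UMIs. Per the labels the genome build was mm10, and per the submitters' processing notes Cell Ranger was used. Per the file headers the version was 7.1.0 for both 2.5-month libraries and 4.0.0 for both 5-month libraries, so version and age coincide fully and no fit with version as a term could be had. Whether reads in introns were counted, and how reads of overlapping genes were assigned, was not given in the sources used here. By the defaults of the software introns are counted in version 7.1.0 and not in 4.0.0, so that intron counting may differ exactly along the age split, in every fold change between the ages and in its relation to gene length. The gene annotation of GENCODE release M21 on GRCm38 (the same assembly as mm10) was used for gene positions and lengths, not for counting. Barcodes shared between pairs of libraries made up 0.0809% to 0.337% of barcodes.

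Nuclei with at least 300 detected genes and at most 5% mitochondrial UMIs were kept, which removed 27 of 32326 barcodes. Doublets were called in each library with scrublet at an expected rate of 0.06 and removed. The caller marked 3 and 1 nuclei at 2.5 months and 672 and 784 at 5 months; a caller that marks under 0.5% has not worked, so doublets stayed in the 2.5-month libraries. Counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes were chosen without any gene of the fixed lists, and 30 principal components with 15 nearest neighbours gave 63 Leiden clusters at resolution 1, of which 59 held at least 20 nuclei (scanpy 1.11.5, leidenalg 0.10.2). All libraries were clustered together without integration. Clusters were named from marker genes fixed before the data were examined. A name needed at least 3 markers raised by a log2 fold change above 1, and a cluster whose leading genes went against its name stayed unnamed. The rules that set aside clusters with mixed rod markers, and the decisions on 5 clusters led by pigment, epithelial or stromal genes, were made after the data were seen. The largest cluster of each class was the same at both ages. Endothelium and striated muscle had under 20 nuclei in some library and were not tested.

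Counts were summed per class and library and turned into counts per 1000000 UMIs (CPM) for display. The sums ranged from 1231180 to 4644350 UMIs in rods, from 3333070 to 8530070 in amacrine cells and from 1198660 to 3441890 in Müller glia, and down to 138040 to 323225 in melanocytes, so that the small classes carry more counting error. Pearson correlations across genes of log CPM in rods were 0.968 and 0.942 within the ages and 0.951 to 0.962 between them; genes are not independent replicates. Intervals and floors of 3 counts cover counting error only.

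Age effects were fitted in each class with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, age as the only term) in R 4.3.3, leaving 2 residual degrees of freedom, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. All such tests were 2-sided and a positive log2 fold change means higher at 5 months. The 25 gene lists, fixed before the data were examined, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 in each class with at least 5 tested members. They covered clock genes of the Per and Dbp phase, clock genes of the Arntl phase, immediate early genes, heat shock, rod phototransduction and outer segment, cone phototransduction, photoreceptor ribbon synapse, ON bipolar cascade, reactive gliosis, glial homeostasis, interferon and MHC class I, complement, nuclear oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, glycolysis, cholesterol synthesis, the unfolded protein response, cohesin with CTCF and lamina, DNA methylation and Polycomb, glutamate receptors, GABA and glycine receptors, inherited retinal disease, free rod RNA and sex chromosomes. The class by age interaction compared rods with each of the 3 next most numerous classes with library as a block. The class map compared each class with the mean of the other classes with library as a block. Shares of nuclei were compared by exact permutation of the 4 libraries.

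Genes were named by a rule fixed before the data were examined: up to 10 higher and 10 lower genes in rods and up to 5 of each in the next 4 most numerous classes, with the smallest adjusted p among called genes with an absolute log2 fold change of at least 0.5 and no overlap of the ages, without symbols of predicted genes and mitochondrial genes, and up to 4 called genes per list and class. Gm44511, Gm42418, Lars2 and genes given as examples of a list that passed only within that list, or did not pass, were chosen after their values were seen. For the class map up to 4 genes per class and list were open to naming. Some single genes are not reported here.

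The fits were tested on simulated counts with 200 changed genes. In rods 2.99%, 43.3% and 87.9% of genes changed 1.5-fold, 2-fold and 4-fold were recovered among 12364, and 0.142% of unchanged genes were called. The latter is a share of 12164 unchanged genes, beside 67, 67 and 66 changed ones. Among the simulated calls in rods, false ones therefore made up more than the 0.05 that the threshold aims at. Unchanged genes were called at 0.162% in amacrine cells and 0.167% in fibroblasts, where the same held, and at 0.00772% in ganglion cells. In 20 simulations lists of 20 genes raised 1.5-fold had an unadjusted p under 0.05 in 100% in rods, and unchanged lists in 0%. The simulated genes varied independently of each other, while the median estimated correlation within the real lists was 0.177. The 0% therefore does not carry over to the list tests reported here. The interaction fit recovered 78.3% of 4-fold changes and the class map 98.5%. Recovery of 2-fold changes was lower in most other classes, 23.9% in Müller glia, 14.9% in melanocytes, 8.96% in fibroblasts and 1.49% in pigment epithelium, where 62.1% of 4-fold changes were recovered. Most 2-fold changes were therefore below what 2 libraries per age can show in these classes.

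Alternatives chosen before the data were examined were DESeq2 1.42.0, relative log expression scaling, no filter on low counts, at least 500 genes per nucleus, at most 1% mitochondrial UMIs, doublets kept, resolution 0.5, class sums thinned to 1 depth, a replicate block, each library left out in turn, an estimated correlation and fry for lists, and nuclei other than rods as denominator. Chosen after seeing the data were 1 doublet score threshold for all libraries (0.152), rods without 1 cluster that came mostly from the first 2.5-month library, and removal of each library's trend over gene length. Spearman correlations of fold change with gene length lay between -0.42 and -0.11 over the classes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.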

Results

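Gene expression was measured in single nuclei of the mouse retina, the light-sensing tissue at the back of the eye, with the 10x droplet method, in which each nucleus receives a barcode and each captured RNA molecule a unique molecular identifier (UMI). There were 4 libraries, each from the left eye of 1 animal: 2 animals were 2.5 months old and 2 were 5 months old. Age was the only difference between the groups that the labels name, and no purpose was stated for the age comparison. The labels call the 2.5-month animals wild type and give no genotype for the 5-month animals. The 2.5-month libraries held 7404 and 7422 barcodes with 19608067 and 28723257 UMIs, and the 5-month libraries held 7537 and 9963 barcodes with 28042269 and 36320257 UMIs. Medians of 1812.5 and 2899.5 UMIs per barcode at 2.5 months stood beside 2744 and 2785 at 5 months. Both 2.5-month libraries were counted with Cell Ranger 7.1.0 and both 5-month libraries with Cell Ranger 4.0.0, per the file headers, so that age and software version cannot be told apart in any difference between the ages. Values after ± are standard deviations over the 2 libraries of an age (n = 2) throughout.

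The nuclei fell into 12 named classes that cover the layers of the retina and its neighbouring tissues. Rods, cones, bipolar, horizontal, amacrine and retinal ganglion neurons, Müller glia, retinal pigment epithelium, fibroblasts, melanocytes, endothelium and striated muscle were each recognised by marker genes, and each name stands for nuclei like that type. Of 32326 barcodes, 30839 nuclei were kept and 28285 of them belonged to a named class. The other 2554 lay in clusters without a clear name, led for example by Myh11 and Acta2 with pigment genes (785 nuclei) or by Cd74 and Lyz2 with epithelial genes (154 nuclei). The unnamed share was 9.18% and 5.39% in the 2.5-month libraries and 8.30% and 9.87% in the 5-month libraries. A small group of 54 nuclei with mixed Müller, cone and rod genes came from the 2.5-month libraries alone, and another of 51 nuclei with cone and rod genes held 50 from those libraries. Both were left out of the classes by a threshold set after the data were seen. The doublet caller marked 8.92% and 7.87% of nuclei at 5 months but 0.0406% and 0.0135% at 2.5 months, where it had not worked, so doublets were removed unequally between the ages.

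The rod share of nuclei was lower and the shares of most other neurons and of Müller glia were higher at 5 months. Rods, the dim-light receptors, made up 45.8 ± 5.68% of named nuclei at 2.5 months and 18.4 ± 5.85% at 5 months, a difference of -27.4 percentage points. Amacrine interneurons were at 15.4 ± 5.34% and 23.4 ± 1.70%, Müller glia at 6.38 ± 0.422% and 16.5 ± 3.17%, cones at 7.89 ± 1.41% and 14.3 ± 1.27%, and ganglion cells, the output neurons, at 3.48 ± 0.453% and 8.70 ± 0.775%. Horizontal cells were at 0.501 ± 0.0971% and 1.76 ± 0.191%. Bipolar cells, which carry photoreceptor signals inward, were at 12.1 ± 2.75% and 8.10 ± 1.38%. The libraries of the ages did not overlap in any of these 7 classes, and each exact permutation test gave p = 0.33, the smallest value that the 6 assignments of 4 libraries allow. Shares of fibroblasts, melanocytes, pigment epithelium, endothelium and muscle overlapped between the ages.

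Because rods were so numerous, their lower share raises every other share. Among nuclei other than rods, Müller glia were still at 11.8% and 20.1%, cones at 14.5% and 17.5%, ganglion cells at 6.51% and 10.7% and horizontal cells at 0.921% and 2.15%, while bipolar cells were at 22.2% and 9.89%. Amacrine cells were at 28.0% and 28.7% with overlapping libraries, so that their difference was not larger than the spread once rods were left out. The smallest rod cluster by UMIs, with a median of 860, gave 1357 nuclei in the first 2.5-month library and 326, 160 and 299 in the others. Rods held the fewest UMIs per nucleus of all classes, with medians of 1092 and 1488 at 2.5 months and 1297.5 and 1089 at 5 months. No barcode held fewer than 500 UMIs, and any effect of barcode selection by depth on the rod share was not tested. The dissociation of the tissue, which can set such shares, was not given in the sources used here.

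**Figure D1:**
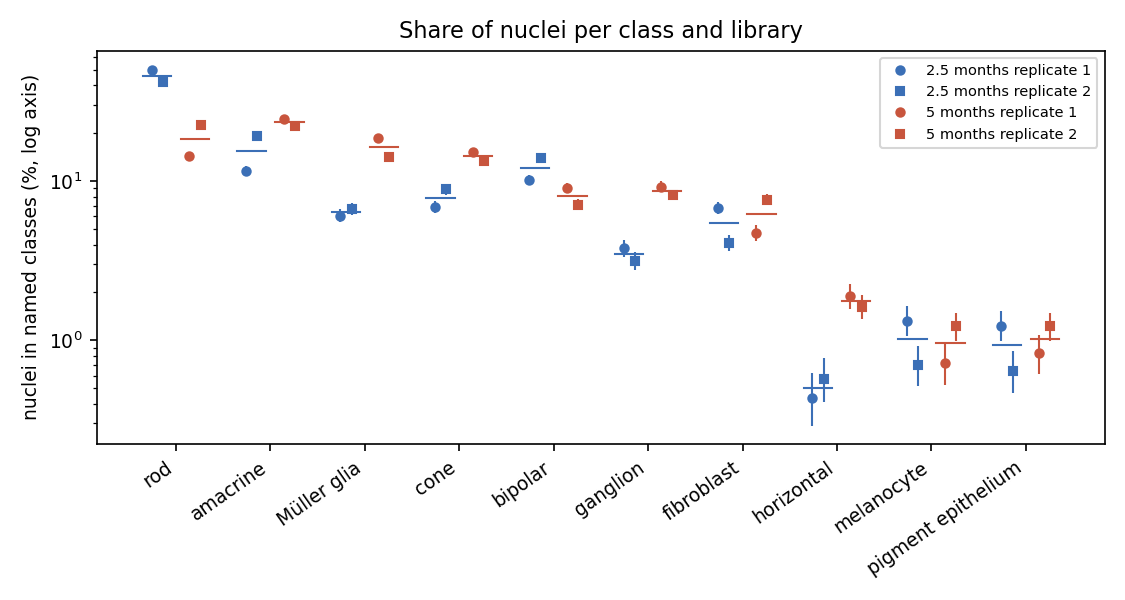
Share of nuclei in named classes (%, log axis) for the 10 classes with at least 20 nuclei in every library. Each point is a library with its exact binomial 95% interval, which covers counting error only, blue for 2.5 months and red for 5 months, with a line at the mean. Rods lie at 45.8% and 18.4% on average, and Müller glia at 6.38% and 16.5%.

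Transcripts of rods, lens and muscle appeared in nuclei of other classes, and their level differed between libraries. The summed level of 18 rod genes, including the arrestin gene Sag, had a median over the non-rod classes of 19.4% and 15.3% of the rod level in the 2.5-month libraries and 16.1% and 12.5% in the 5-month libraries. Lens genes such as the crystallin gene Cryaa summed to 228 and 50 counts per 1000000 UMIs (CPM) in rods at 2.5 months and to 4.87 and 3.58 CPM at 5 months. Striated muscle genes summed to 394 CPM in rods of the first 2.5-month library, against 57.9, 97.5 and 50.1 CPM in the other libraries. Xist, the RNA of the inactive X chromosome, was at 0.562 and 2275 CPM at 2.5 months and at 1.64 and 2271 CPM at 5 months. The 4 Y-linked genes summed to 632 and 1.57 CPM and to 498 and 4.35 CPM in the same libraries, so that each age held 1 library of either kind.

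A handful of genes separated the ages in most classes. Rps2 and Rps21, which encode proteins of the small ribosomal subunit, fell in 9 and 8 of the 10 classes tested. Cmss1, which encodes a protein linked to small ribosomal subunit assembly, and Gm44511 rose in 6 classes each, Cdk8, the kinase of the Mediator complex, in 5, and the cytoskeletal pseudokinase gene Peak1, the cytokine receptor gene Il31ra and the histone H4 gene Hist1h4d in 4 each (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). In rods, Rps2 was at 120 ± 40.0 CPM at 2.5 months and 6.42 ± 1.39 CPM at 5 months (log2 fold change -4.27, SE 0.343, adjusted p = 0.0109), and Rps21 at 277 ± 125 and 24.2 ± 7.43 CPM (log2 fold change -3.47, adjusted p = 0.0250). In Müller glia, Cmss1 was at 495 ± 207 and 2818 ± 497 CPM (log2 fold change 2.50, SE 0.278, adjusted p = 0.00625).

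Each of these 8 genes had the same sign and an unadjusted p under 0.05 in every class where it was tested, 10 classes for most, 9 for Il31ra and 8 for Hist1h4d. The log2 fold change ran from -3.47 to -2.49 for Rps21, from 2.06 to 2.69 for Cmss1, from 1.1 to 1.64 for Gm44511, from 0.95 to 1.73 for Cdk8, from 0.71 to 2.06 for Peak1, from 2.08 to 3.10 for Il31ra and from 2.06 to 3.62 for Hist1h4d. For Rps2 it ran from -4.66 to -3.40 in the 8 classes with more than 1 UMI at 5 months. In horizontal cells Rps2 had 35 UMIs at 2.5 months and 1 UMI at 5 months, a ratio of 95.0-fold lower (exact 95% counting interval 16 to 3858), and in melanocytes 32 and 1, a ratio of 30.9-fold lower (5.16 to 1257). On GRCm38, Rps2 (ENSMUSG00000044533) lies at chr17:24718116-24721929, Rps21 (ENSMUSG00000039001) at chr2:180257377-180258445, Cmss1 (ENSMUSG00000022748) at chr16:57302000-57606864, Gm44511 at chr6:128780285-128826315, Cdk8 at chr5:146231230-146302874, Peak1 at chr9:56201126-56418067, Il31ra at chr13:112519898-112594360 and Hist1h4d at chr13:23581598-23582735. Rps2 overlaps Snhg9 on the other strand, Cmss1 encloses Filip1l on the other strand, and Gm44511 shares its span with Klrb1c and Klrb1b, so that these values are uncertain where reads of overlapping genes were split.

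**Figure D2:**
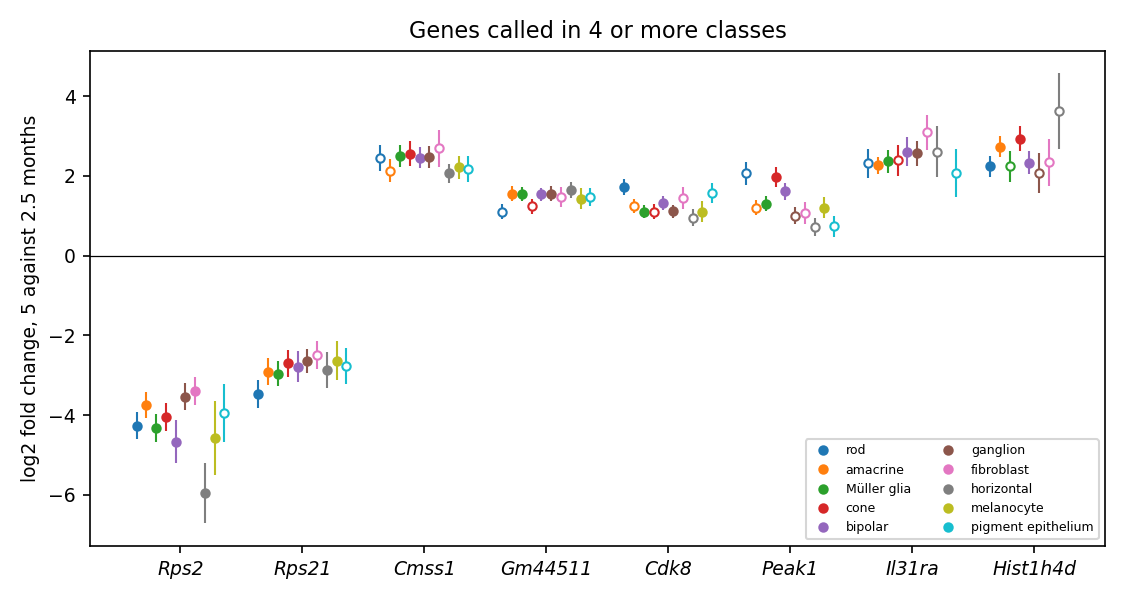
Log2 fold change (5 against 2.5 months) with its standard error for the 8 genes called in 4 or more classes, 1 colour per class. Filled points passed the adjusted threshold and open points did not. Rps2 and Rps21 lie below 0 and the other 6 genes above 0 in every class where they were tested.

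Few other genes passed in single classes. In rods 3 genes rose and 3 fell among 12364 tested, and Snhg11, a host gene of small nucleolar RNAs, rose from 47.8 ± 1.28 to 183 ± 33.7 CPM (log2 fold change 1.95, SE 0.190, adjusted p = 0.0250, chr2:158375638-158386145), with Cdk8 at a log2 fold change of 1.73 and Hist1h4d at 2.24. Müller glia had 8 higher and 4 lower genes of 12581, among them Camk1d, a calcium-dependent kinase gene (152 ± 87.7 to 688 ± 115 CPM, log2 fold change 2.15, adjusted p = 0.0239, 1.68 to 2.93 with 1 library left out, chr2:5293457-5714515), Il31ra at 2.36, Snhg11 at 2.10 and Peak1 at 1.30. Camk1d and Snhg11 were each called in 2 classes and were higher in all 10 tested. Their unadjusted p by edgeR was under 0.05 in 9 and 5 classes. The log2 fold changes ran from 0.38 to 2.15 and from 0.21 to 2.10, so that neither rise was confined to the classes named. The lens crystallin genes Crybb2 (chr5:113058258-113070117) and Cryaa (chr17:31677807-31681733) passed in Müller glia and were lower at an unadjusted p under 0.05 in 7 of the 7 classes where each was tested. In Müller glia Crybb2 had 62 UMIs at 2.5 months and 0 at 5 months. That was 42.6-fold lower against a floor of 3 UMIs over the 5-month group (lower exact 95% counting bound 33.6-fold). Cryaa had 67 and 1 UMIs, a ratio of 138-fold lower (exact 95% counting interval 23.9 to 5529). Most of this level came from the first 2.5-month library, with Crybb2 at 32.3 and 11.5 CPM in the 2. Without 1 library the log2 fold change of Cryaa ran from -8.56 to -5.85 and that of Crybb2 from -9.35 to -8.01. With 0 UMIs of Crybb2 at 5 months, its values here come from the fit and are not measured folds. Amacrine cells had 3 higher and 2 lower of 15294, cones 3 and 3 of 11512, bipolar cells 6 and 2 of 11552, ganglion cells 5 and 3 of 13413 and horizontal cells 3 and 4 of 7221. In amacrine cells Il31ra rose from 10.2 ± 0.265 to 49.1 ± 7.59 CPM (log2 fold change 2.27, adjusted p = 0.00956), and in cones Hist1h4d rose from 5.48 ± 0.104 to 42.4 ± 2.64 CPM (log2 fold change 2.93, adjusted p = 0.0150).

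Melanocytes had 7 higher and 24 lower genes of 5078, among them the synaptic genes Syt1 (log2 fold change -1.68, adjusted p = 0.00640) and Cacnb2 (-1.95, adjusted p = 0.0110), the glutamate receptor gene Grm8 (-1.45, adjusted p = 0.0219) and the mitochondrial gene mt-Co1 (-1.14, adjusted p = 0.0494). That set depended on the tool, doublets, depth and single libraries. Without the first 5-month library 4 genes were higher and 0 lower, class sums thinned to 1 depth gave 2 and 0, and the replicate block 1 and 0. DESeq2 called 1 gene, 1 doublet threshold for all libraries gave 8, and with called doublets kept 31 genes were higher and 3 lower, with Syt1 at 0.62. The log2 fold change ran from -2.56 to -1.37 for Syt1 and from -2.55 to -1.27 for Cacnb2 with 1 library left out. Free rod RNA in melanocyte nuclei fell too, from 8235 and 6519 to 5723 and 4752 CPM, and Grm8 was at 1286 CPM in rods. Fibroblasts had 0 higher and 1 lower gene of 11885, Rps2, by edgeR, with 580 higher at an unadjusted p under 0.05 and 19 higher by DESeq2. The pigment epithelium had 1 higher and 0 lower gene of 6262 by edgeR, with 202 lower at an unadjusted p under 0.05 and 5 lower by DESeq2.

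In total 43 genes were called in at least 1 class, 5 of them in 5 or more classes and 31 in 1 class, 23 of these in melanocytes alone. The libraries of the ages did not overlap for 35.1% to 40.5% of the genes tested in a class, where chance gives 33.3%. With another scaling (relative log expression) the higher and lower calls were 8 and 3 in cones, 1 and 2 in fibroblasts and 6 and 8 in pigment epithelium. With the trend of fold change over gene length removed they were 1 and 3 in rods, 7 and 3 in amacrine cells, 5 and 3 in cones, 4 and 3 in bipolar cells, 8 and 3 in ganglion cells, 1 and 2 in fibroblasts, 15 and 28 in melanocytes and 6 and 10 in pigment epithelium. Without the second 5-month library 2 genes were called in rods, with 1 of the 6 kept, and 0 in ganglion cells. Without the first 5-month library 0 were called in amacrine cells. Without the second 2.5-month library the numbers were 50, 110 and 77 in rods, amacrine and ganglion cells, and without the first 22, 96 and 29. The log2 fold change of every named gene kept its sign with each library left out. With 1 library left out called genes ranged from 20 to 49 in Müller glia, 12 to 72 in cones, 9 to 64 in bipolar cells, 13 to 98 in horizontal cells, 61 to 261 in fibroblasts and 32 to 262 in pigment epithelium. Replicate number coincides with the split in Xist and Y-linked genes at both ages, which the fit leaves out. With it as a replicate block 67 genes were called in rods, 88 in amacrine cells, 106 in fibroblasts and 1 in melanocytes.

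The 25 gene lists were compared between the ages in each class with camera, a 2-sided test of whether a list's genes move more than other genes, at a preset correlation of 0.01 and with Benjamini-Hochberg adjustment over 238 tests. There 83 tests passed. With an estimated correlation 0 passed (lowest adjusted p = 0.901, 5 at an unadjusted p under 0.05), and by fry, which asks whether a list moves one way on balance, 0 passed (lowest adjusted p = 0.439, 13 at an unadjusted p under 0.05). Each list result that follows therefore passed with the preset correlation alone. In 26 of the 83 the list's median log2 fold change had the opposite sign without 1 of the 4 libraries.

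Immediate early genes, the fast transcriptional response to neuronal activity and to stress, fell at 5 months in amacrine, bipolar and ganglion neurons and in Müller glia. The list was tested in 7 classes and passed in these 4. The median log2 fold change was -1.19 in bipolar cells (10 of 12 members negative, adjusted p = 3.27e-14 by camera), -0.95 in ganglion cells (14 of 15, 3.39e-20), -0.75 in amacrine cells (15 of 18, 4.63e-12) and -0.36 in Müller glia (7 of 11, 0.00998). In each the adjusted p was 0.901 with an estimated correlation. In bipolar cells Egr1 was at 84.0 ± 15.4 and 12.8 ± 13.2 CPM, Fos at 36.8 ± 2.74 and 10.2 ± 6.21 CPM and Nr4a1 at 83.5 ± 14.7 and 30.8 ± 13.3 CPM. In amacrine cells Egr1 was at 43.4 ± 2.66 and 10.3 ± 7.23 CPM. In ganglion cells Nr4a3 (chr4:48045153-48086447) fell from 23.6 ± 1.83 to 4.17 ± 1.87 CPM (log2 fold change -2.52, adjusted p = 0.0124 over all genes by edgeR), and Nr4a2 was at 5.85 ± 1.78 and 0.551 ± 0.331 CPM. Over all genes 0, 1, 0 and 0 members passed in bipolar, ganglion, amacrine and Müller nuclei, and 8, 10, 7 and 1 did so adjusted over the list alone, all lower. With 1 library left out the median was -0.460 without the first 2.5-month library in amacrine cells, -0.607 without the second 5-month library in ganglion cells, and in Müller glia -0.156 without the first 5-month library and -0.636 without the second. The summed list was also lower without overlap of the libraries in horizontal cells (198 and 158 against 107 and 122 CPM) and melanocytes (414 and 369 against 232 and 343). Its libraries overlapped in rods, cones, fibroblasts and pigment epithelium.

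Interferon and MHC class I genes, which serve antiviral defence and antigen display, rose at 5 months in 5 classes. In Müller glia 23 of 24 members were positive with a median of 0.85 (adjusted p = 1.63e-08 by camera). Medians were 0.62 in bipolar cells (adjusted p = 0.00757), 0.54 in ganglion cells (0.00700), 0.54 in amacrine cells (0.0243) and 0.33 in fibroblasts (0.00482), and in each class the adjusted p = 0.901 with an estimated correlation. Microglia markers were also higher at 5 months in these 5 classes without overlap of the libraries, at 104 and 99.3 against 107 and 157 CPM in Müller glia, 67.3 and 52.7 against 71.6 and 101 in bipolar, 79.9 and 65.4 against 97.2 and 114 in ganglion and 90 and 83.4 against 92.7 and 141 in amacrine cells, with 113 and 110 against 143 and 243 in fibroblasts. The same held for these markers outside the 5 classes, in rods (81.4 and 73.6 against 123 and 120 CPM) and cones (64.1 and 51.9 against 94.4 and 85.5). It held in pigment epithelium too (149 and 132 against 153 and 190 CPM), so that the rise was not particular to the 5 classes. In interferon genes the libraries of 5 months differed widely. In Müller glia Bst2 was at 11.6 and 6.48 CPM at 2.5 months and at 102 and 14.9 CPM at 5 months. Without the first 5-month library the median was 0.0188 in Müller glia, -0.0348 in amacrine, -0.119 in bipolar and 0.305 in ganglion cells, and in fibroblasts it was -0.149 without the second 2.5-month library. Over all fits without 1 library the medians ran up to 1.32, 0.827, 1.29, 0.918 and 1.08 in Müller, amacrine, bipolar, ganglion and fibroblast nuclei, and the amacrine median was 0.0553 without the second 2.5-month library. No member passed in these classes over all genes or adjusted over the list alone by edgeR. Bst2 (log2 fold change 2.75), Isg15 (1.67) and Ifi27 (1.44) had unadjusted p-values of 0.00376, 0.00579 and 0.00920 in Müller glia.

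**Figure D3:**
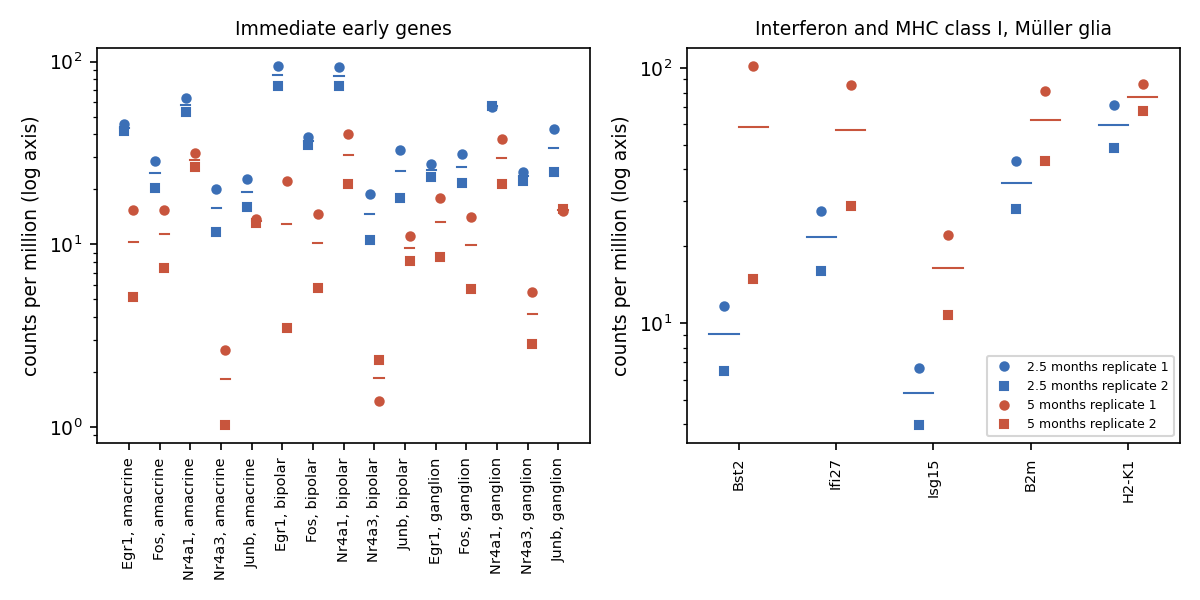
CPM (log axis) of immediate early genes in amacrine, bipolar and ganglion nuclei (left) and of interferon and MHC class I genes in Müller glia (right), each point a library and each line the mean of an age, blue for 2.5 months and red for 5 months. Egr1 in bipolar cells lies at 84.0 and 12.8 CPM on average, and Bst2 in Müller glia at 102 CPM in the first and 14.9 CPM in the second 5-month library.

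The glial homeostasis list rose at 5 months in Müller glia, which support retinal neurons (13 of 14 members positive, median 0.27, adjusted p = 6.02e-05 by camera; adjusted p = 0.901 with an estimated correlation). Hes1, a Notch target, was at 318 ± 52.9 and 552 ± 49.6 CPM, and the water channel gene Aqp4 at 355 ± 20.9 and 524 ± 27.5 CPM. With the lipid carrier gene Apoe (log2 fold change 1.03) these 3 passed adjusted over the list alone and 0 over all genes. The list also rose in pigment epithelium (0.30, adjusted p = 0.0269) and fell in bipolar (-0.36, 0.000243), ganglion (-0.37, 0.000957) and horizontal cells (-0.38, 0.0372), where its genes are not typical. With 1 doublet threshold for all libraries these last 3 had adjusted p-values of 0.370, 0.376 and 0.987, and each of the 4 had an adjusted p = 0.901 with an estimated correlation.

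Reactive gliosis genes fell in rods (median -0.63, adjusted p = 1.58e-07 by camera), amacrine cells (-0.55, 2.23e-06), bipolar cells (-0.50, 2.92e-05), ganglion cells (-0.30, 0.00923) and Müller glia (-0.10, 0.0147) and rose in fibroblasts (0.32, 0.0445). In each the adjusted p was 0.901 with an estimated correlation. Gfap, the intermediate filament gene of reactive glia, was at 7.22 ± 0.339 and 0.925 ± 0.378 CPM in Müller glia, and with Stat3 (log2 fold change -0.71) passed adjusted over the list alone. In rods Gfap was at 10.0 ± 0.272 and 1.73 ± 0.117 CPM and was 1 of 3 members to do so. Astrocyte markers, which include Gfap itself, summed in rods to 38.9 and 30.1 CPM at 2.5 months and to 15.4 and 24.2 CPM at 5 months. Their sums were also lower without overlap in amacrine (21.0 and 16.8 against 9.55 and 16.6 CPM) and ganglion cells (19.6 and 23.6 against 12.5 and 18.1). In fibroblasts they were higher without overlap (90.4 and 111 against 122 and 145 CPM). The libraries overlapped in Müller glia (68.4 and 62.5 against 56.0 and 70.0 CPM) and bipolar cells (29.1 and 23.4 against 24.3 and 28.7). Over all genes 0 list members passed in Müller glia or rods. The Müller glia median was 0.0261 without the first 5-month library, and the fibroblast median -0.114 without the second. Complement genes rose in fibroblasts (7 of 7 positive, median 0.89, adjusted p = 0.000210), where C4b was at 77.0 ± 17.5 and 234 ± 23.5 CPM and passed adjusted over the list alone, and fell in amacrine cells (-0.24, 0.0452). Microglia markers in fibroblast nuclei summed to 113 and 110 CPM at 2.5 months and to 143 and 243 CPM at 5 months. Both had an adjusted p = 0.901 with an estimated correlation. The fibroblast median ran from 0.414 without the second 5-month library to 1.51 without the first 2.5-month library.

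Glycolysis genes rose in horizontal cells (15 of 17 positive, median 0.37, adjusted p = 9.33e-05 by camera), cones (17 of 20, 0.30, 0.000957), amacrine cells (0.33, 0.00757), Müller glia (0.18, 0.0107), pigment epithelium (0.29, 0.0256) and bipolar cells (0.21, 0.0474), with 0 members passing over all genes or adjusted over the list alone. Nuclear genes of oxidative phosphorylation rose in cones (0.25, 0.00636) and horizontal cells (0.18, 0.0347), but their medians were -0.0439 and -0.00260 without the second 2.5-month library, and the glycolysis median in bipolar cells was -0.0657 without the first 5-month library. Mitochondrially encoded transcripts, which in nuclei come from outside the nucleus, rose in fibroblasts (12 of 12, 0.94, 1.48e-10; 7 adjusted over the list alone) and pigment epithelium (0.89, 0.00141) and fell in Müller glia (11 of 11, -0.60, 4.01e-08; 4 adjusted over the list alone), melanocytes (-0.85, 7.17e-08), amacrine cells (-0.53, 0.00430) and bipolar cells (-0.37, 0.0260). The amacrine and bipolar medians were 0.0497 and 0.321 without the first 2.5-month library, whose median mitochondrial share of 0.208% stood above 0.0860%, 0.0970% and 0.0930% in the others, and the pigment epithelium median was -0.163 without the second 5-month library. The adjusted p was 0.901 with an estimated correlation for each of these except oxidative phosphorylation in cones, with an adjusted p = 0.918.

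Ribosomal protein genes fell in rods (25 of 31 negative, median -0.22, adjusted p = 5.92e-07 by camera), ganglion cells (-0.24, 7.90e-06), amacrine cells (-0.16, 5.09e-05), Müller glia (-0.11, 0.00299) and bipolar cells (-0.088, 0.0379) and rose in fibroblasts (0.60, 0.0167) and pigment epithelium (0.44, 0.0379). With an estimated correlation the adjusted p = 0.901 in rods, ganglion and amacrine cells, adjusted p = 0.918 in Müller glia and adjusted p = 0.938 in the other 3. Of the list's members Rps2 alone passed over all genes, in 6 of these classes (Rps21, called in 8 classes, is not on the list), and rods had 3 members adjusted over the list alone, Rps2, Rplp2 and Rps18. Without the first 2.5-month library the medians were 0.116, 0.167, 0.296, 0.271 and 0.441 in rods, ganglion, amacrine, Müller and bipolar nuclei, and without the second 5-month library -0.170 in fibroblasts and -0.224 in pigment epithelium. Genes of cholesterol synthesis rose in horizontal cells (12 of 12 positive, 0.38, 0.0242) and fell in amacrine cells (-0.13, 0.0398), and genes of the unfolded protein response, which relieves protein stress in the endoplasmic reticulum, rose in fibroblasts (16 of 16 positive, 0.50, 0.00206; 0.00811 without the second 5-month library). Each of these 3 had an adjusted p = 0.901 with an estimated correlation and 0 members adjusted over the list alone.

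Photoreceptor genes fell outside the photoreceptors, together with the rod transcripts used as a measure of free RNA. The rod phototransduction and outer segment list fell in amacrine cells (25 of 25 negative, median -0.42, adjusted p = 1.23e-12 by camera), ganglion cells (-0.52, 1.40e-11), melanocytes (-0.60, 6.83e-06), fibroblasts (-0.44, 2.72e-05) and bipolar cells (-0.25, 0.000606), and passed in neither rods nor cones. The free rod RNA list, which shares most of its genes, fell in the same 5 classes with medians of -0.42, -0.53, -0.48, -0.24 and -0.20. Without the first 2.5-month library its medians in bipolar cells and fibroblasts were 0.0537 and 0.112. The cone phototransduction list fell in ganglion (10 of 10 negative, -0.88, 3.38e-09), amacrine (-0.34, 0.000108), horizontal (-0.56, 0.0118) and bipolar cells (-0.24, 0.0335), with 5, 2, 1 and 1 members such as the cone opsin gene Opn1mw passing adjusted over the list alone. With 1 doublet threshold for all libraries these 4 had adjusted p-values of 0.322, 0.946, 0.435 and 0.169. The adjusted p was 0.901 with an estimated correlation for each list and class here except the free rod RNA list in fibroblasts, with an adjusted p = 0.918.

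Synaptic and receptor lists fell in melanocytes, fibroblasts and pigment epithelium, and glutamate receptor genes rose in photoreceptors. Photoreceptor ribbon synapse genes fell in melanocytes (13 of 15 negative, median -0.90, adjusted p = 5.81e-10 by camera; 2 members over all genes and 7 adjusted over the list alone), fibroblasts (-0.39, 7.00e-07), ganglion cells (-0.14, 0.00282) and pigment epithelium (-0.20, 0.0313). Glutamate receptor genes fell in fibroblasts (20 of 21, -0.62, 2.98e-09), pigment epithelium (-0.75, 7.32e-06) and melanocytes (-0.91, 0.00168) and rose in rods (0.34, 0.0106) and cones (0.45, 0.0200), where the medians were -0.182 and 0.0229 without the first 5-month library. In rods Gria2 was at 90.5 ± 6.49 and 154 ± 5.51 CPM and was the 1 member to pass adjusted over the list alone. Over all libraries Gria2 was at 1165 CPM in amacrine and 1063 CPM in ganglion cells, and carry-over of such transcripts into rods was not tested. ON bipolar cascade genes fell in ganglion cells (-0.46, 0.000957), fibroblasts (-0.37, 0.00313) and amacrine cells (-0.22, 0.0167), and GABA and glycine receptor genes in fibroblasts (-0.48, 0.000315) and amacrine cells (-0.19, 0.0350). Free rod RNA was at 8235 and 6519 against 5723 and 4752 CPM in melanocytes and at 8122 and 5426 against 6506 and 4916 CPM in fibroblasts, lower without overlap of the libraries in melanocytes and with overlap in fibroblasts, so that carried-over rod transcripts were lower beside the synaptic genes in melanocytes at least. Each of these 14 results had an adjusted p = 0.901 with an estimated correlation. With 1 doublet threshold for all libraries the ON bipolar and GABA and glycine receptor results were lost in every class named, and so were ribbon synapse genes in fibroblasts and pigment epithelium and glutamate receptor genes in the same 2 classes, with a fibroblast glutamate receptor median of 0.284.

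Genes of inherited retinal disease fell in 7 classes, with medians of -0.34 in amacrine cells (74 of 86 negative, adjusted p = 7.57e-11 by camera), -0.34 in ganglion cells (1.83e-10), -0.25 in fibroblasts (3.75e-05), -0.41 in melanocytes (6.02e-05), -0.14 in bipolar cells (0.000392), -0.089 in horizontal cells (0.0398) and -0.11 in Müller glia (0.0474). The adjusted p = 0.901 with an estimated correlation, and adjusted p = 0.918 in Müller glia. With 1 doublet threshold the result was kept in amacrine and ganglion cells and lost in the other 5. The list holds many photoreceptor genes, and Sag, which also is a free rod RNA gene, was the 1 member of these classes to pass adjusted over the list alone, in melanocytes (log2 fold change -0.99).

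Of 10 classes 2 had lower levels of genes that fold and anchor chromatin by camera. The cohesin, CTCF and lamina list had a median of -0.19 in amacrine cells (16 of 22 negative, adjusted p = 0.00915 by camera) and -0.11 in cones (16 of 22, 0.0313), with an adjusted p = 0.901 with an estimated correlation in both and 0 members adjusted over the list alone. The median was negative in all 10 classes, from -0.22 to -0.077. The DNA methylation and Polycomb list passed camera in 0 of 10 classes (lowest adjusted p = 0.274, 0 at an unadjusted p under 0.05 by camera, by fry or with an estimated correlation). Clock genes of the Per and Dbp phase passed in 0 of 10 classes (lowest adjusted p = 0.0831, 2 at an unadjusted p under 0.05 by camera, 1 by fry and 0 with an estimated correlation) and those of the Arntl phase in 0 of 9 (lowest adjusted p = 0.0986, 1 by camera, 0 by fry and 0 with an estimated correlation). Heat shock genes passed in 0 of 10 (lowest adjusted p = 0.0537, 2 by camera, 1 by fry and 0 with an estimated correlation), and the sex chromosome list in 0 of 10 (lowest adjusted p = 0.784, 0 at an unadjusted p under 0.05 by any of these).

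The age difference itself differed between rods and other classes for a small number of genes. Against rods, 6 of 13760 genes differed in Müller glia, 5 of 14923 in amacrine cells and 1 of 12497 in cones (edgeR test of the class by age interaction with library as block). Camk1d had a log2 fold change of 2.15 in Müller glia and 0.56 in rods, a difference of 1.68 (adjusted p = 0.000374). Meg3, a long noncoding RNA of an imprinted locus, was at 1.46 in rods and -0.19 in Müller glia (difference -1.64, adjusted p = 4.45e-05), and Snhg11 at 1.95 in rods and 0.53 in amacrine cells (difference -1.43, adjusted p = 0.0263). Gngt2, a cone transducin gene, was at 0.82 in cones and -0.07 in rods (difference 0.92, adjusted p = 0.0133). At an unadjusted p under 0.05 there were 907, 1271 and 956 genes. The counts without 1 library ran from 4 to 93 in Müller glia, from 16 to 264 in amacrine cells and from 0 to 82 in cones.

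Across the 4 libraries, many disease and receptor genes had a single class of highest expression. Of 70 inherited retinal disease genes tested, with 18 naming markers left out, 45 mapped to 1 class: 19 to rods, 13 to cones, 3 each to Müller glia, bipolar cells and pigment epithelium, and 2 each to horizontal cells and melanocytes. A gene mapped where its log2 fold change over the mean of the other classes was above 1 with an adjusted p under 0.05 (edgeR, library as block) and its CPM was highest in that class in all 4 libraries. In rods Impg1, a matrix proteoglycan gene, stood 4.61 above the mean of the other classes on the log2 scale and Abca4, a retinoid transporter gene, 3.79, with cones next at 496 against 871 CPM and 746 against 1366 CPM. In cones the cone channel gene Cnga3 stood 6.51 and the protocadherin gene Pcdh15 5.23 above. Clrn1 (6.09) and Crb1 (4.90) mapped to Müller glia, Nyx (6.21) and Gpr179 (5.09) to bipolar cells, Ndp (4.64) to horizontal cells, Kcnj13 (4.99) to melanocytes, and Mertk, the receptor for engulfing outer segments (5.92), to pigment epithelium. Kcnj13 was at 643 ± 170 CPM in melanocytes and 451 ± 174 CPM in pigment epithelium (SD, n = 4). Each of these had an adjusted p of at most 6.53e-17.

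Many receptor genes were highest in 1 class. Of 22 GABA and glycine receptor genes 16 mapped, 8 of them to bipolar cells, led by Glra1 (6.39) and the GABA receptor gene Gabrr2 (5.57). Amacrine cells held Glra2 (5.05) among 3, ganglion cells Gabra2 (4.15) among 3 and pigment epithelium Gabra4 (4.77) among 2. Gabra2 was at 422 CPM in ganglion and 384 CPM in amacrine cells. Of 23 glutamate receptor genes 16 mapped, 6 to amacrine cells with Grik2 (4.12), 4 to ganglion cells with the NMDA subunit gene Grin2a (5.93), 3 to bipolar cells with Grm5 (5.55) and 2 to horizontal cells with Gria3 (4.0). Each mapped gene named here had an adjusted p of at most 1.37e-14 by edgeR. Of 22 cohesin, CTCF and lamina genes 2 mapped, Lmnb1, a nuclear lamin gene, to rods (109 ± 6.91 CPM over 4 libraries, log2 fold change 2.27) and Hdac8 to melanocytes (1.45). Of 21 DNA methylation and Polycomb genes 5 mapped, among them Tet3 to rods (1.21), Tet1 to Müller glia (1.89), Cbx7 to cones (1.18) and Ezh2 to bipolar cells (1.28).

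**Figure D4:**
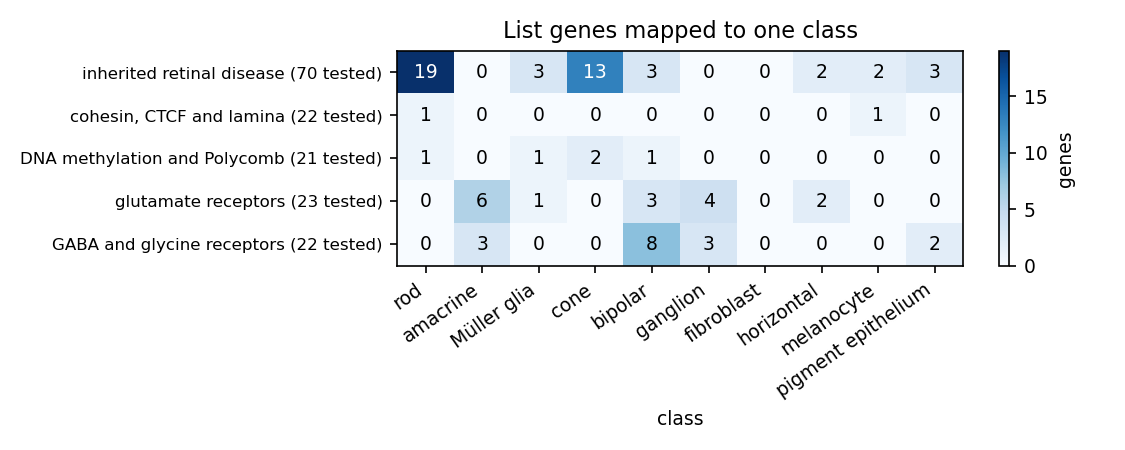
Number of genes of 5 lists (vertical) that mapped to each of 10 classes (horizontal), with the number tested beside each list name. Rods and cones hold 19 and 13 of the 45 mapped inherited retinal disease genes, and bipolar cells 8 of the 16 mapped GABA and glycine receptor genes.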

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

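All tests of a difference in age effect between rods and another class were planned, while the genes were singled out by their result. Each gene named here was picked out because its age effect differed between rods and another class by the edgeR interaction test at an adjusted p under 0.05; no explanation was tested for any of them.

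In Müller glia against rods the difference in log2 fold change was -1.64 for Meg3, a noncoding RNA of an imprinted locus (1.46 in rods and -0.19 in Müller glia), and 1.60 for AC149090.1 (-2.29 and -0.74). It was 1.68 for the calcium-dependent kinase gene Camk1d (0.56 and 2.15), and 1.15 for the matrix protein gene Sparc (-0.78 and 0.34). It was -1.45 for Arap2 (1.61 and 0.15) and 2.31 for Rarres2, which encodes the secreted protein chemerin (-1.55 and 0.82). Adjusted p-values ran from 4.45e-05 for Meg3 to 0.0252 for Rarres2. Fitted class by class, Camk1d was higher in all 10 classes and AC149090.1 was higher in 0 of 10. Their unadjusted p by edgeR was under 0.05 in 9 and 10 classes, so that these 2 genes differed in size and not in direction.

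In amacrine cells against rods the difference was -1.65 for the cone arrestin gene Arr3 (0.73 in rods and -0.87 in amacrine cells), -2.14 for the secreted neurexophilin gene Nxph1 (1.25 and -0.91), -1.59 for Meg3 (1.46 and -0.12), 1.27 for AC149090.1 (-2.29 and -1.03) and -1.43 for Snhg11 (1.95 and 0.53). Adjusted p-values ran from 0.00147 for Arr3 to 0.0263 for Snhg11. Arr3 is a naming marker of cones, so that its values in rods and amacrine cells may include cone transcripts. The cone phototransduction list, which holds Arr3, did not pass in amacrine cells with 1 doublet threshold for all libraries. In cones against rods the difference was 0.92 for the cone transducin gene Gngt2 (-0.07 and 0.82, adjusted p = 0.0133). Meg3 and AC149090.1 differed against rods in both Müller glia and amacrine cells, comparisons that share the rod libraries and are not independent.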

How the results depend on the processing

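The results with 1 doublet threshold, with the gene length trend removed and without 1 rod cluster were tests chosen only after the result was seen. The other alternatives were planned, and the cause of a change was not tested unless stated. With 2 libraries per age, depth and number of animals limit what can pass. The 39 named gene results were refitted 587 times: 510 kept direction and call, 76 kept direction and lost the call, 35 of these with 1 library left out, and 1 changed direction, Syt1 in melanocytes (0.62 with called doublets kept). All 5 named melanocyte genes lost the call with DESeq2. Rps2 kept its call in Müller glia, cones and horizontal cells under every alternative in which it was tested there.

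Numbers of called genes moved by over 1.5 times as follows. DESeq2 called 24 in rods, 31 in amacrine, 21 in Müller, 20 in cone, 14 in bipolar, 14 in ganglion, 39 in fibroblast, 1 in melanocyte and 11 in pigment epithelium nuclei. Relative log expression scaling gave 11 in cones, 3 in fibroblasts and 14 in pigment epithelium, and 23 and 9 genes for the interaction in amacrine cells and cones. Without a filter on low counts, where many genes have a few UMIs, there were 138 in rods, 237 in amacrine, 133 in Müller, 69 in cone, 106 in bipolar, 131 in ganglion, 294 in fibroblast, 74 in horizontal, 61 in melanocyte and 102 in pigment epithelium nuclei. The interaction then gave 90, 23 and 21 genes in amacrine, Müller and cone nuclei. At most 1% mitochondrial UMIs and resolution 0.5 each gave 0 in pigment epithelium by edgeR. With doublets kept there were 15 in cones, 5 in fibroblasts, 4 in horizontal cells and 3 in pigment epithelium. Class sums thinned to 1 depth, which hold fewer UMIs, gave 4 in bipolar cells, 0 in fibroblasts, 2 in horizontal cells, 2 in melanocytes and 0 in pigment epithelium by edgeR.

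With the gene length trend removed there were 10 genes in amacrine cells, 3 in fibroblasts and 16 in pigment epithelium, and 3 lists in pigment epithelium. With 1 doublet threshold there were 10 genes in cones, 5 in fibroblasts, 8 in melanocytes and 16 in pigment epithelium, and 21 for the interaction in cones. Lists were then 5 in bipolar, 7 in ganglion, 8 in fibroblast, 3 in horizontal and 3 in pigment epithelium nuclei. An estimated correlation and fry each gave 0 lists in every one of the 10 classes.

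With the replicate block, genes called were 67 in rods, 88 in amacrine, 54 in Müller, 35 in cone, 52 in bipolar, 48 in ganglion, 106 in fibroblast, 11 in horizontal, 1 in melanocyte and 73 in pigment epithelium nuclei. The numbers name different animals, and deviations of same-numbered libraries correlated between -0.195 and 0.0157, so the numbers do not pair the samples. They coincide with the split in Xist and Y-linked genes, so that the block stands for that split too. These correlations do not show that such a term is unneeded.

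With 1 library left out, which leaves 1 sample in an age that is assumed to vary like the other age, called genes ranged from 2 to 119 in rods, 0 to 110 in amacrine, 20 to 49 in Müller, 12 to 72 in cone, 9 to 64 in bipolar, 0 to 77 in ganglion, 61 to 261 in fibroblast, 13 to 98 in horizontal, 4 to 33 in melanocyte and 32 to 262 in pigment epithelium nuclei. The 0 in amacrine cells came without the first 5-month library and the 0 in ganglion cells without the second, by edgeR. Called lists ranged from 4 to 8 in rods, 10 to 13 in amacrine, 7 to 10 in Müller, 4 to 7 in cone, 5 to 11 in bipolar, 9 to 14 in ganglion, 8 to 14 in fibroblast, 1 to 8 in horizontal, 6 to 9 in melanocyte and 1 to 8 in pigment epithelium nuclei. Of 83 called lists, 10, 4, 7 and 8 had a median of the opposite sign without the first and second 2.5-month and the first and second 5-month library. The interaction ranged from 16 to 264 genes in amacrine, 4 to 93 in Müller and 0 to 82 in cone nuclei. Mapped genes ranged from 46 to 51 for inherited retinal disease, 2 to 3 for cohesin, CTCF and lamina, 5 to 6 for DNA methylation and Polycomb, 15 to 17 for glutamate receptors and 17 to 18 for GABA and glycine receptors. Fewer libraries make the demand on all libraries easier to meet.

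Share differences without 1 library ranged from -31.5 to -23.2 points for rods, 4.28 to 11.8 for amacrine, 7.85 to 12.3 for Müller, 5.43 to 7.43 for cone, -5.95 to -2.06 for bipolar, 4.67 to 5.76 for ganglion, 1.12 to 1.39 for horizontal, -0.711 to 2.22 for fibroblast, -0.359 to 0.270 for melanocyte and -0.214 to 0.383 for pigment epithelium nuclei. Among nuclei other than rods the fibroblast and pigment epithelium differences turned to -2.58 and -0.514 points, and with doublets kept the melanocyte difference turned to 0.108 points.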

Other observations

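Tests of free RNA per droplet, of ribosomal RNA reads, of software version at single genes, of doublet removal, those on the 3 neuron classes alone and those of the share of a fall that was lost were chosen only after the result was seen; the other tests were written down before it.

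Some chromatin regulators differed in level between classes. Lmnb1 was at 109 ± 6.91 CPM in rods over the 4 libraries (SD, n = 4), with cones next. Tet1 and Tet3, which oxidise methylated cytosine, were highest in different classes, Tet1 in Müller glia (123 ± 4.46 CPM) and Tet3 in rods (207 ± 23.6 CPM), without being confined to them: Tet1 was at 80.6 CPM in bipolar and 76.6 CPM in amacrine cells, and Tet3 at 121 CPM in cones. The transcripts Gm42418 and Lars2 were higher at 5 months in 10 of 10 classes with an unadjusted p under 0.05 in each, but passed in 0 (edgeR, lowest adjusted p = 0.128); their log2 fold changes ran from 1.04 to 1.64 and from 0.84 to 1.59.

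Rps2 and Rps21 were lower and Cmss1, Gm44511, Il31ra and Cdk8 higher at 5 months in nearly every class. Reads of ribosomal RNA should within an age follow Gm42418, which was judged by the median ratio between the library with more Gm42418 and the other. For Gm44511 and Cdk8 together it was 0.959 at 2.5 months and 0.938 at 5 months. Such reads are argued against for Gm44511, at 0.892 and 1.01. They stay open for Cdk8, at 1.13 and 0.847, which moved the same way as Cmss1 and Il31ra. For Cmss1 and Il31ra they stay open too, with 1.69 at 2.5 months but 0.676 at 5 months. Each age gave 1 pair of libraries. Free RNA at 1 level per droplet stays open, since UMIs per nucleus differed 2.81-fold between the highest and lowest class (2.16 to 12.6 over the 6 genes); an earlier ratio on CPM, 1.92, was void because depth per nucleus differs 6.63-fold between classes. A candidate explanation is the change of Cell Ranger version, which cannot be told apart from age because 0 ages hold libraries of both versions; genes with named processed pseudogenes lay 0.000512 from matched genes, which decides nothing because 1 of the 6 genes has such a pseudogene and the length-matched difference was -0.0955. An effect of age itself was not tested apart from version.

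Lens crystallin transcripts Cryaa and Crybb2 appeared in every class at 2.5 months. Free lens RNA at 1 level per droplet may account for them in the retinal classes, where UMIs per nucleus differed by at most 1.95-fold in 1 library and 1.63-fold in the other over classes with at least 10 such UMIs (horizontal cells held 1 UMI in the second library and were left out there). The same free RNA alone is argued against in fibroblasts, melanocytes and pigment epithelium, whose median UMIs per nucleus lay 1.90 and 3.80 times above the retinal classes. The CPM ratio planned for this, 29.1, exceeded its bound but was void for the same difference in depth. How far the lens was removed from each eye, and any biological source, was not tested.

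Immediate early genes were lower at 5 months in amacrine, bipolar, ganglion and Müller nuclei. Free RNA at 1 level per droplet is argued against, since UMIs of the list per nucleus differed 10.9-fold and 11.3-fold between classes in the 2.5-month libraries (a CPM ratio of 3.73 was void because of depth). At 1 doublet threshold the list passed camera with the preset correlation in all 4 classes. Its medians closest to 0 were -0.301 in Müller glia and -0.753 in the 3 neuron classes. Their upper bootstrap bounds reached 0.259 and -0.0936, so that the medians alone decided nothing. Unequal doublet removal as the whole cause is argued against by the change gene by gene. That measure lost at most 9.75% of the fall in Müller glia and 2.21% in the neuron classes (upper bootstrap bounds). Without either 2.5-month library the median in the 3 neuron classes was -0.460 or lower, with an upper bound of 0.109, which alone decides nothing. Gene by gene at most 41.4% of the fall was lost there, which argues against handling of 1 such library as the whole cause. In Müller glia it stays open (-0.318, a loss of up to 84.4%). The bound on the share lost was set after the medians were seen. All bootstrap bounds here cover spread over the list's genes, which are not independent, and hold no spread between libraries. What they argue against therefore concerns these 4 libraries alone. Age, handling of both libraries, time of day or light before sampling might each contribute and were not tested.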
